A study of Homo sapiens with 12 samples.

How the data were processed

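Total RNA was extracted from CT27 cells with Trizol on days 0, 3, 6 and 8 of extravillous differentiation, copied to cDNA and sequenced on a NovaSeq instrument, per the labels' protocols. The labels put 3 libraries in each of 4 groups and their cell type field names the end cell type even for day 0, which the titles call the stem state, so groups here follow the day alone. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC 0.11.9, R 4.2.2 and DESeq2 1.38.3. They also name the builds GRCh38.p13 and Rnor_5.0, the latter a rat build, without saying what each was for. The gene IDs are human Ensembl IDs. The aligner, the counter, its strand setting and the annotation are not given in the sources used here, so reads of a gene and an antisense partner, or of near-identical paralogs, cannot be told apart.

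The authors deposited 1 table whose values are a signal of gene counts divided by size factors, that is, normalized counts, per the file headers and the values themselves. Each library's values were whole multiples of a single step, which is 1 divided by its size factor. Dividing by the step gave whole reads for 100% of values within 0.01, and size factors from 0.627 to 1.44. The table held 9237 rows for 9145 gene IDs, since 92 rows repeated an ID with identical values and were dropped. Each gene's day 8 and day 0 means differed by at least 1.5-fold, so the table is a selection of genes by that difference. Calls between day 8 and day 0 follow from the selection, and other comparisons are conditional on it. Housekeeping genes and most ribosomal protein genes were not analysed here. All 9145 IDs matched a symbol, 9101 matched a GENCODE 29 gene (GRCh38), which gave coordinates, and 8521 of these are protein coding.

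The number of reads recovered per library, 9650118 to 21649352, covers the table's genes and is not the library depth. A gene of 10 normalized counts rests on about that many reads per library, and p-values and SDs cover such counting error together with the spread between cultures. No pair of replicates agreed within sampling noise, so none were merged.

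The planned test was edgeR's quasi-likelihood test on raw counts with a spread shared by all days. The deposited unit is a normalized value, and the main test became limma 3.58.1 on log2(normalized count + 1) in R 4.3.3. Fold changes are on that scale, which understates the change of genes with few counts. The recovered reads also allow edgeR, which was run on them as an alternative. At day 8 against day 6 edgeR called 2137 genes, against 4348 in the main fit. All 12 libraries entered 1 fit with a mean per day, robust moderation of the spread, two-sided tests, Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Genes needed at least 10 normalized counts in at least 3 libraries, which left 8898. In simulated data each gene had its mean over the 12 libraries, and each day had 1 spread, estimated over genes. In each simulation 200 genes and a list of 20 were changed after day 0. With 1 spread shared by all days, 59.1% of calls for day 3 against day 0 were false and 2.62% of unchanged genes were called (8740 genes). Day 0 libraries spread far more than the rest. The fit therefore took precision weights from each day's own trend of spread on mean. After this 10.1% of such calls were false, still above the 0.05 threshold, and 0.165% of unchanged genes were called. This choice followed the simulation, not the real calls. Changed means an adjusted p below 0.05, and the number at least 2-fold changed is given beside it.

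The comparisons were day 3 against day 0, day 6 against day 3, day 8 against day 6 and day 8 against day 0. Day 6 against day 0 served the timing classes. In a separate test across the 4 days 8888 genes changed. Genes were classed by the first day on which they were called against day 0 in their final direction. Turning genes were called at both steps around a day, in opposite directions, each at least 2-fold, and were set beside 20 simulations of unchanged groups and the overlap of independent lists.

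Before the data were examined, 36 gene lists were written down from general knowledge. They cover stem state, pan-trophoblast, extravillous, syncytiotrophoblast, pregnancy-specific glycoprotein and trophoblast transcription factor genes, G1/S, G2/M and cyclin genes, epithelial junctions, mesenchymal genes, integrins, basement membrane, matrix proteases, and HLA class I with antigen presentation. They also cover WNT, Notch, TGF-beta and ERBB genes, interferon response, cholesterol synthesis, glycolysis with hypoxia, oxidative phosphorylation, mitochondrial and ribosomal genes, unfolded protein response, immediate early genes, p53 targets, imprinted genes, angiogenic factors and cytokines. The last 5 hold markers of stromal, endothelial, leukocyte, erythroid and amnion or early embryonic cells. Lists with at least 5 tested members, 34 in all, were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, with adjustment over lists. No list passed at 0.05 with the estimated correlation in any of the 4 comparisons. The test fry was also planned and run. Of 136 list tests over the 4 comparisons, it called 69 that camera at its preset correlation did not, in the same direction. List p-values in the results are from camera unless fry is named. Lists overlap: extravillous genes recur among the proteases, transcription factors and angiogenic factors.

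Genes were named by a rule set beforehand. It took for each comparison the 8 largest rises and falls among called genes with a mean of at least 2 on the log2 CPM scale of the recovered reads and no overlap between days, 17 landmark genes, up to 4 members with the largest changes per list, and the 6 clearest turning genes per direction. Genes named outside it are HLA-A, MX1, IFNAR1 and IFNAR2 at day 6 against day 3, chosen after their values were seen.

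Alternatives were RLE, upper quartile and TMM factors or library totals, 2 other filters, DESeq2 1.42.0 and limma-voom on the recovered reads, a spread without robust moderation, fits of only the 2 groups compared, the replicate number as a block, each library left out, thinning to the smallest total, a test against a 2-fold change, other pseudocounts, library weights and 1 shared spread. Library totals here are sums of the recovered reads of the table's selected genes, not library depths. edgeR 4.0.16 on the recovered reads called 6675, 6165, 2137 and 8898 genes in the comparisons in the order above.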

Results

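RNA of CT27 cells, an established human trophoblast stem cell line, was sequenced along a protocol that turns the stem cells into extravillous trophoblast, the invasive cell type of the placenta. The 12 libraries fell into 4 groups, 3 each at day 0, the stem state, and at days 3, 6 and 8. The deposited table held normalized counts for 9145 genes, and whole reads were recovered from it. The recovered reads of these genes came to between 9650118 and 21649352 per library, lowest in day 3 replicate 1 and highest in day 8 replicate 3. The table was a selection in which day 8 and day 0 means lay at least 1.5-fold apart for each gene, 4264 being higher and 4881 lower at day 8. These totals are therefore not library depths, and each statement holds for these genes only. The labels describe the replicates as biological replicates of a single line, so p-values measure the spread between these samples and not between donors.

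Among these selected genes the days separated far more than the replicates. Selection for a difference between days 8 and 0 favours such a separation and an axis between those days. In the principal components of the 500 most variable genes, the first carried 87.4% of the variance and ran from day 0 through day 3 to days 6 and 8. The second, with 9.47%, set day 3 apart from the other days. The day 0 libraries spread more than the rest. A coefficient of variation beyond counting error, from 1 dispersion per day fitted over genes together, was 30.4% at day 0. It was 2.67% at day 3, 4.57% at day 6 and 4.42% at day 8. Day 0 replicate 1 stood apart, with 662 genes at least 2-fold above the mean of the other day 0 libraries and 431 at least 2-fold below it. The same counts were 79 and 380 for replicate 2, and 9 and 128 for replicate 3. MKI67, a proliferation marker, was at 3508 normalized counts in replicate 1 and at 11052 and 9860 in replicates 2 and 3.

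**Figure D1:**
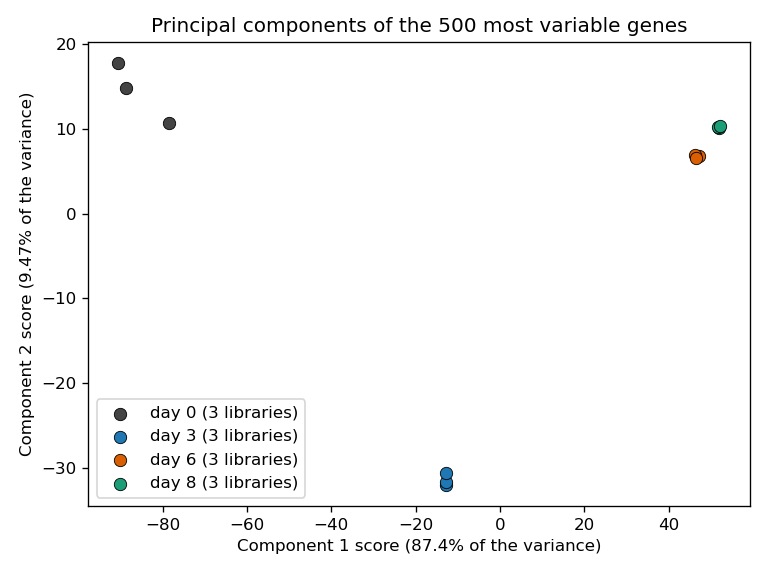
Scores of the 12 libraries on the first component (horizontal, 87.4% of the variance) and the second (vertical, 9.47%), each point 1 library, coloured by day. Day 0 libraries lie between -90.5 and -78.6 on the first component, day 3 libraries at -12.8, and those of days 6 and 8 between 46.3 and 52.2.

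The first comparison, day 3 against day 0, covers the cells' first step out of the stem state. Placental genes that were almost unread at day 0 were high by day 3. HTRA4, a placental serine protease, rose from 28 ± 33.4 to 14820 ± 287 normalized counts (SD, n = 3 per day, here and below). INSL4, an insulin-like placental peptide, rose from 12.7 ± 7.68 to 3135 ± 12, and TREML2 from 3.54 ± 2.46 to 6512 ± 385. ANGPT4, an angiopoietin, rose from 16.3 ± 19.2 to 9155 ± 152. EGR1, an immediate early transcription factor, went the other way, from 10750 ± 5450 to 91.8 ± 15.8. HMGA2, a chromatin protein of growing cells, fell from 1850 ± 719 to 23.3 ± 5.57, and PODXL, a sialomucin of the cell surface, from 20950 ± 9310 to 404.9 ± 11.2. Across the 8898 genes tested, 6130 changed, 2874 higher and 3256 lower at day 3, and 3838 of these moved at least 2-fold (limma, Benjamini-Hochberg adjusted p below 0.05).

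Syncytiotrophoblast genes, of the fused hormone-secreting layer of the placenta, moved furthest among the lists at this step. Of the 23 tested, 21 rose and 0 fell, 21 changed when adjusted over the list alone, and the median log2 fold change was 5.84 (camera adjusted p = 4.01e-10, adjusted p = 0.121 with an estimated correlation). The fusion protein gene ERVW-1 rose by 2.68 ± 0.179 on the log2 scale (SE) and SDC1, a syndecan of the syncytial surface, by 4.25 ± 0.181. ERVV-1, an endogenous retroviral envelope gene, reached 11140 ± 435 from 67.5 ± 76.8, and INHA, an inhibin subunit, 810.1 ± 47.4 from 2.87 ± 2.21. At day 0 the median of this list already lay 0.85 above the day 0 mean in replicate 1, against -0.54 and -0.30 in replicates 2 and 3.

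Extravillous genes also rose at day 3, 22 of 29 tested members being higher and 3 lower, with 25 changed when adjusted over the list alone and a median of 2.21 (camera adjusted p = 3.51e-06, adjusted p = 0.323 with an estimated correlation). The gelatinase MMP2 went from 1847 ± 172 to 37710 ± 953, and the collagen-binding integrin ITGA1 from 136.3 ± 101 to 2243 ± 53.1. The HLA class I gene HLA-G, which marks extravillous cells, rose from 919.8 ± 569 to 4640 ± 179. NOTUM, a secreted inhibitor of WNT proteins, was still low at day 3, at 738.4 ± 60.6 against 406.3 ± 431 at day 0 (adjusted p = 0.0273), a call lost without day 0 replicate 2 or replicate 3, where the log2 fold changes were 1.09 and 0.85. HPGD, a prostaglandin-degrading enzyme, was among the members that fell, from 638.8 ± 431 to 69.6 ± 9.43.

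Transcription factors of the trophoblast moved with these genes, 24 of 30 tested being higher and 4 lower, with 29 changed when adjusted over the list alone (camera adjusted p = 6.15e-06, adjusted p = 0.323 with an estimated correlation). DLX5 and DLX6, neighbouring homeobox genes, rose by 4.57 ± 0.525 and 4.86 ± 0.566 on the log2 scale. ASCL2 rose by 2.45 ± 0.265 and SNAI1 by 2.04 ± 0.23. HAND1 fell from 2441 ± 809 to 93.5 ± 13.8. Unfolded protein response genes rose as a group, 15 of 16 tested, and 15 also when adjusted over the list alone (camera adjusted p = 1.51e-06, adjusted p = 0.139 with an estimated correlation). Among them DNAJB9, a chaperone of the endoplasmic reticulum, went from 287.7 ± 15.4 to 2024 ± 71.8. Of 25 matrix protease and inhibitor genes, 14 rose and 6 fell, 20 changing over the list alone (camera adjusted p = 0.0159, adjusted p = 0.323 with an estimated correlation). The glycolysis and hypoxia list had 13 of 25 members higher and 2 lower, 13 changing over the list alone (camera adjusted p = 0.0426, adjusted p = 0.686 with an estimated correlation). Its members included the glucose transporter SLC2A1, up by 1.80 ± 0.177, and the peptide hormone ADM, up by 2.42 ± 0.23. That list's p was 0.0904 with edgeR on the recovered reads.

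Stem state genes were split at day 3, with 4 of 16 higher and 8 lower, 12 changing over the list alone. The list did not pass camera (camera adjusted p = 0.448), while fry called it lower (fry adjusted p = 0.00142). TEAD4, a transcription factor of trophoblast progenitors, fell from 3089 ± 81.7 to 621.1 ± 23.4, and LRP2, a large endocytic receptor, from 69990 ± 11500 to 8893 ± 283. TP63, a progenitor transcription factor, was at 439.2 ± 60.3 and then 330.5 ± 21.2 (adjusted p = 0.0674; called without day 0 replicate 1, at -0.52), and NOTCH1 at 1703 ± 222 and 1660 ± 72.2 (adjusted p = 0.865). The 10 tested pan-trophoblast genes gave 7 higher and 1 lower, 8 over the list alone (camera adjusted p = 0.0539).

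Counts of changed cell cycle genes depended on the day 0 libraries. Of 48 G2/M genes, 0 rose and 13 fell, and 8 changed when adjusted over the list alone (camera adjusted p = 0.153). Without day 0 replicate 1, in which the list's median lay 0.86 below the day 0 mean, 47 of the 48 fell and the list was called lower (camera adjusted p = 6.81e-08), as it was under library totals. MKI67 was at 8140 ± 4060 at day 0 and 6882 ± 157 at day 3 (adjusted p = 0.781). Without day 0 replicate 1 its log2 fold change was -0.60 and passed the test. The G1/S list had 12 of 41 higher, among them RRM2, a subunit of ribonucleotide reductase, and 9 lower, 15 changing over the list alone (camera adjusted p = 0.634). Without day 0 replicate 1 the G1/S counts were 8 and 18, and under library totals 5 and 16. The cyclin and E2F list gave 7 of 23 higher and 7 lower, against 8 and 11 without day 0 replicate 1 and 6 and 10 under library totals, with 14 over the list alone (camera adjusted p = 0.763). CCNE1, the G1/S cyclin E1, rose by 3.10 ± 0.208 on the log2 scale while CCND2, a D-type cyclin, fell by 3.63 ± 0.255.

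Mesenchymal and stromal genes went both ways, more of them down than up. Of 21 mesenchymal genes 13 fell and 5 rose, 18 over the list alone (camera adjusted p = 0.0539), and of 12 stromal markers 6 fell and 3 rose, 9 over the list alone (camera adjusted p = 0.391). VIM, the intermediate filament of mesenchymal cells, had 135.3, 123.8 and 151.9 normalized counts in the day 0 libraries and 0 in the 9 later ones. THBS1, a matrix glycoprotein, fell from 4395 ± 2300 to 251 ± 26.7. CCN2, a matricellular gene induced by TGF-beta and YAP, fell from 996.6 ± 315 to 13.6 ± 2.4. The ERBB list, with 5 of 18 higher and 8 lower and 14 over the list alone (camera adjusted p = 0.607), held large falls of EGR1 and of the ligand AREG, from 68.9 ± 45.8 to 0.28 ± 0.49. In the immediate early and heat shock list 6 of 16 rose and 8 fell, 14 over the list alone (camera adjusted p = 0.674), JUN going from 1055 ± 406 to 79 ± 16.7. Leukocyte markers gave 1 of 5 higher and 3 lower, 4 over the list alone (camera adjusted p = 0.642).

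The counts at this step moved with single day 0 libraries, from 5137 changed genes without replicate 3 to 7287 without replicate 1, and 46.9% of calls were higher, against 28% under library totals and 52.4% with library weights. In simulated data of this comparison the test found 10.3% of genes changed by 1.5-fold, 58.5% of those changed by 2-fold and 98.3% of those changed by 4-fold, with 10.1% false calls among all calls over 8740 genes. Each simulation changed only 200 genes and a list of 20. The real step called a far larger share of genes, and both kinds of rate depend on the share changed. They therefore do not carry over to the real calls.

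The second comparison, day 6 against day 3, was the step at which all tested extravillous genes rose. Placental lactogen CSH1 went from 166.9 ± 31.2 to 125000 ± 8850 normalized counts, and its near-identical neighbour CSH2 from 177.9 ± 21.5 to 68240 ± 5540. NOTUM rose from 738.4 ± 60.6 to 128600 ± 12700. VCAN, a matrix proteoglycan, rose from 3.48 ± 0.41 to 1306 ± 194, and SCUBE1, a secreted surface protein gene, from 2.91 ± 1.33 to 1869 ± 249. Among the largest single falls were those of S100A16, a calcium-binding protein gene, from 1033 ± 74 to 18.9 ± 5.11, LRP2 from 8893 ± 283 to 300.2 ± 15.7, and GJA1, the gap junction protein connexin 43, from 551.6 ± 8.57 to 28.4 ± 10.9. In all 6974 genes changed, 3439 higher and 3535 lower, with 3255 moving at least 2-fold (limma, adjusted p below 0.05).

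Each of the 29 tested extravillous genes rose, 29 also when adjusted over the list alone, with a median of 3.38 (camera adjusted p = 3.73e-14, adjusted p = 0.136 with an estimated correlation). HLA-G rose to 58930 ± 5200, MMP2 to 165200 ± 16200, ITGA1 to 22230 ± 168 and the fibronectin receptor ITGA5 to 114800 ± 11300. LVRN, the placental aminopeptidase laeverin, rose by 6.36 ± 0.136 on the log2 scale, PAPPA2, a metalloproteinase, by 5.59 ± 0.423, and PLAC8 by 5.59 ± 0.209. Matrix proteases and inhibitors gave 19 of 25 higher and 4 lower, 23 over the list alone (camera adjusted p = 0.000113, adjusted p = 0.136 with an estimated correlation), led by ADAM12, from 928.3 ± 62.3 to 40480 ± 5200. Pregnancy-specific glycoproteins rose, 9 of 9, and 9 over the list alone (camera adjusted p = 5.06e-06, adjusted p = 0.313 with an estimated correlation). PSG1 rose by 3.92 ± 0.066 and PSG2 by 3.66 ± 0.053, though members of this family, like CSH1 and CSH2, are similar enough that reads could be split between them.

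Of the 23 syncytiotrophoblast genes 15 rose and 7 fell at this step, 22 over the list alone (camera adjusted p = 0.106). Camera on the edgeR fit of the recovered reads, the test first planned, called the list higher (adjusted p = 3.13e-05), while the other camera settings did not call it. SDC1 and ERVW-1 each rose by 0.18 ± 0.039. This direction turned to -0.23 for both when libraries were scaled only by the total recovered reads of the table's genes, which are not library depths.

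Antigen presentation and interferon-response genes rose together with these genes. In the HLA class I and antigen presentation list 14 of 17 rose and 1 fell, 15 over the list alone (camera adjusted p = 6.7e-05, adjusted p = 0.313 with an estimated correlation). HLA-F rose from 53.8 ± 9.25 to 1135 ± 11.2, the peptide transporter subunit TAP2 from 436.4 ± 31.6 to 6102 ± 341, and the immunoproteasome subunit PSMB8 from 7.78 ± 4.12 to 168.8 ± 4.39. HLA genes share sequence, so their reads are uncertain as to the member, and HLA-A stayed low, at 18.8 ± 6.84 and 8.37 ± 2.43. Of 30 type I interferon response genes 29 rose and 0 fell, 29 over the list alone (camera adjusted p = 5.66e-07, adjusted p = 0.346 with an estimated correlation). MX1, an antiviral GTPase, went from 110.1 ± 15.3 to 2456 ± 459, IFI27 from 43.4 ± 8.07 to 1488 ± 169, and IFIT5 from 8.74 ± 4 to 336.6 ± 28.1. The leukocyte markers CD74 and LAPTM5 went the other way, with log2 fold changes of -2.74 ± 0.273 and -4.29 ± 0.906. Their list had 3 of 5 higher and 2 lower (2 and 2 under library totals), 5 over the list alone, with a median of 0.85 and a mean of -0.60 (camera adjusted p = 0.842).

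Cell cycle genes fell. All 48 tested G2/M genes were lower, 48 over the list alone, with a median of -2.39 (camera adjusted p = 1.81e-13, adjusted p = 0.353 with an estimated correlation). G1/S genes fell in 40 of 41 cases, 40 over the list alone (camera adjusted p = 5.71e-12, adjusted p = 0.346 with an estimated correlation). MKI67 went from 6882 ± 157 to 1115 ± 22.3, CDC6, a licensing factor of DNA replication, from 2818 ± 3.95 to 306.4 ± 9.11, and the mitotic activator CDC20 from 2276 ± 59.5 to 216 ± 25.5. Of 23 cyclin, inhibitor and E2F genes 17 fell and 3 rose, 20 over the list alone (camera adjusted p = 0.000766, adjusted p = 0.313 with an estimated correlation), with CCND1, cyclin D1, going from 4484 ± 92.9 to 289.8 ± 40. In the p53 target list 11 of 17 fell and 2 rose, 13 over the list alone (camera adjusted p = 0.0439, adjusted p = 0.313 with an estimated correlation).

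Stem state genes also fell at this step, 13 of 16 lower and 2 higher, 15 over the list alone (camera adjusted p = 0.000744, adjusted p = 0.313 with an estimated correlation). TEAD4 fell from 621.1 ± 23.4 to 72.7 ± 9.27 and TP63 from 330.5 ± 21.2 to 64.9 ± 19.2. PEG10, a retrotransposon-derived imprinted gene, fell by 3.26 ± 0.055, and NOTCH1 by 2.08 ± 0.067 on the log2 scale. Of 22 epithelial junction genes 14 fell and 6 rose, 20 over the list alone (camera adjusted p = 0.0463, adjusted p = 0.315 with an estimated correlation). EPCAM, an epithelial adhesion molecule, went from 2295 ± 48.1 to 184.2 ± 35.4. Of 52 listed nuclear genes of oxidative phosphorylation 24 were tested. Among these 22 fell and 1 rose, 23 over the list alone, mostly by little, with a median of -0.47 (camera adjusted p = 0.000179, adjusted p = 0.346 with an estimated correlation). CYC1, cytochrome c1, was at 2451 ± 146 and then 1231 ± 46.8, and COX6C was the member that rose, from 1526 ± 27.5 to 3055 ± 121.

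Genes of mesenchymal, stromal and vascular cells moved both ways. Of 21 mesenchymal genes 9 rose and 7 fell (7 and 7 under library totals), 16 over the list alone (camera adjusted p = 0.633), fibronectin FN1 going from 13240 ± 629 to 215400 ± 24900 and SPARC from 3313 ± 79.5 to 45030 ± 2150. Of 12 stromal markers 4 rose and 5 fell, 9 over the list alone, with a median of -0.06 and a mean of 0.07 (camera adjusted p = 0.956). Of 7 endothelial markers 4 rose and 1 fell, 5 over the list alone (camera adjusted p = 0.207), including VWF, von Willebrand factor, from 20.8 ± 5.82 to 355.4 ± 15.2. FLT1, a VEGF receptor that placental cells also make, rose by 4.66 ± 0.247 in an angiogenic list with 9 of 16 higher and 4 lower, 13 over the list alone (camera adjusted p = 0.207). The junction and p53 list calls were each lost under several other settings, with adjusted p up to 0.0723 for junctions without day 6 replicate 2 and 0.0645 for p53 targets under library totals. Scaling by library totals lowered the share of higher calls from 49.3% to 31.5%.

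**Figure D2:**
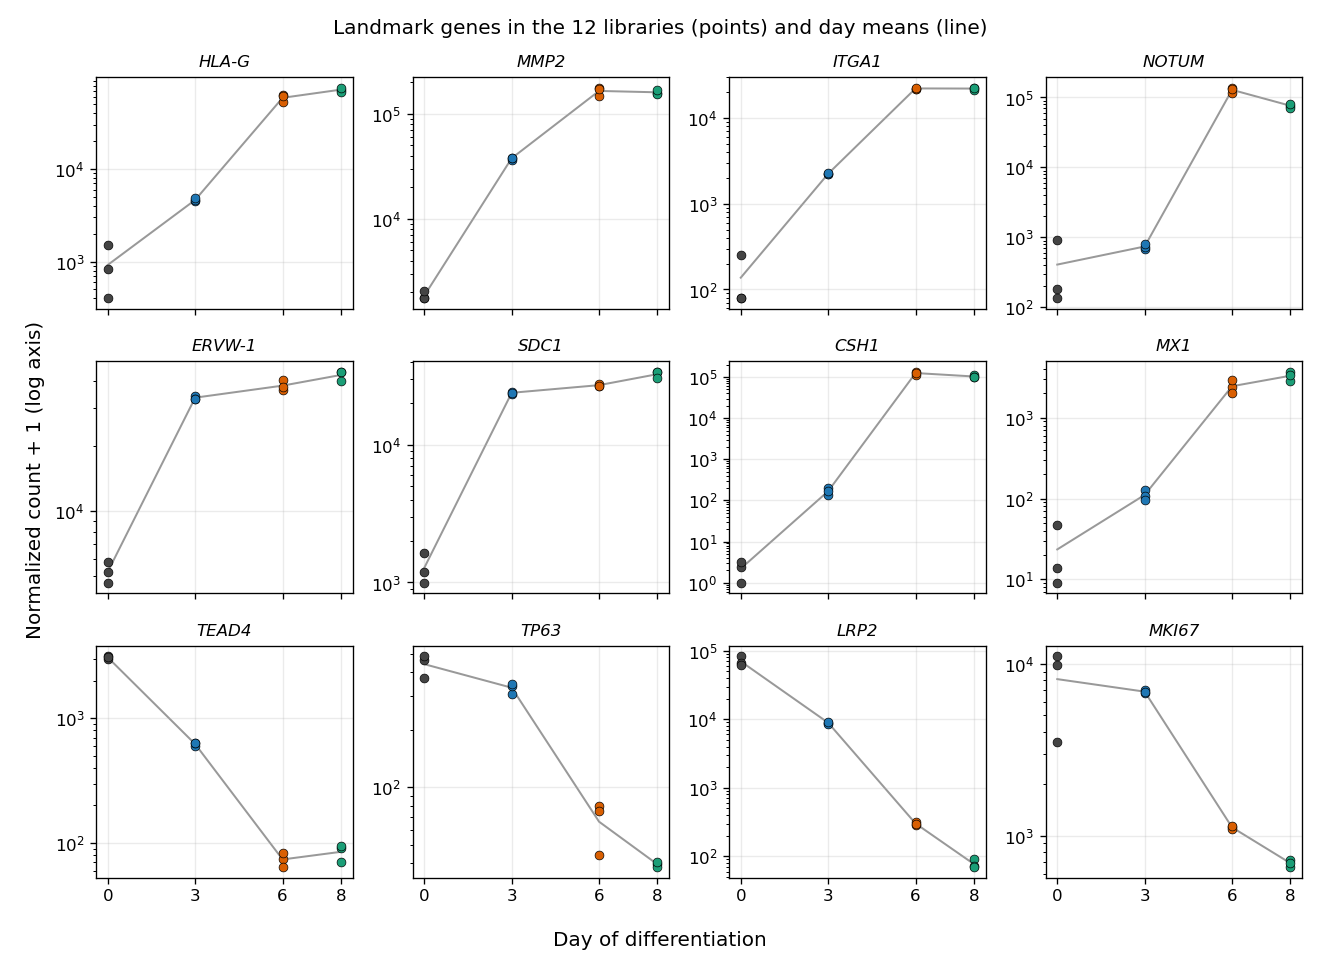
Normalized count plus 1 (vertical, log axis) of 12 genes at days 0, 3, 6 and 8 (horizontal), each point 1 library and the line joining day means. HLA-G, NOTUM, CSH1 and MX1 climb most between days 3 and 6, MMP2, ITGA1, SDC1 and ERVW-1 between days 0 and 3, and TEAD4, TP63, LRP2 and MKI67 end below their day 0 values.

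The third comparison, day 8 against day 6, showed smaller changes. IL3RA, an interleukin 3 receptor subunit, rose from 33.4 ± 15.9 to 166.5 ± 22.4 normalized counts, DPP10 from 152.3 ± 24.1 to 572.2 ± 22.1, and WNT3A, a WNT ligand, from 86.2 ± 28.8 to 310.9 ± 38.6. ANGPT4 fell from 3852 ± 123 to 388.2 ± 7.22, FABP5, a fatty acid binding protein gene, from 392.6 ± 42.4 to 48.1 ± 4.06, and MICB, a ligand of the NKG2D receptor of natural killer cells, from 275.5 ± 10.7 to 64.1 ± 2.76. Across the 8898 genes 4348 changed, 1653 higher and 2695 lower, but only 626 of them at least 2-fold. MMP2 was at 160300 ± 7690 (adjusted p = 0.602) and ITGA1 at 22130 ± 560 (adjusted p = 0.929, its fold change turning to 0.12 under library totals). HLA-G rose by 0.30 ± 0.078 on the log2 scale and NOTUM fell by 0.75 ± 0.106. DESeq2, limma-voom and edgeR called neither gene at nearly the same fold changes, 0.29 to 0.30 for HLA-G and -0.75 for NOTUM. The extravillous list gave 8 of 29 higher and 13 lower (11 and 10 under library totals), 21 over the list alone (camera adjusted p = 0.319). Of the 23 syncytiotrophoblast genes 10 rose and 7 fell, 17 over the list alone (camera adjusted p = 0.176).

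Interferon-response genes were the list that kept rising, 25 of 30 higher and 1 lower, 26 over the list alone, with a median of 0.69 (camera adjusted p = 4.56e-10, adjusted p = 0.348 with an estimated correlation). IFIT2 went from 70.4 ± 5.38 to 338.5 ± 122, IFIT3 from 164.6 ± 11.6 to 625.3 ± 190, and the oligoadenylate synthetase OAS1 from 39.8 ± 1.53 to 137.4 ± 38.5. The antigen presentation list did not follow, with 2 of 17 higher and 8 lower, 10 over the list alone (camera adjusted p = 0.139). PSMB8 fell to 58.9 ± 12.8 and TAP2 to 3477 ± 95.1.

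Most tested genes of energy metabolism were lower at day 8. Tested were 5 of 13 listed mitochondrially encoded genes, 24 of 52 nuclear oxidative phosphorylation genes and 25 of 35 glycolysis and hypoxia genes. Members outside the selected table are not covered. All 5 tested mitochondrially encoded genes fell, 5 over the list alone (camera adjusted p = 0.000307, adjusted p = 0.348 with an estimated correlation), MT-ATP6 going from 129200 ± 7050 to 78290 ± 4320. Nuclear oxidative phosphorylation genes fell in 19 of 24 cases, 19 over the list alone, with a median of -0.27 (camera adjusted p = 0.000864, adjusted p = 0.368 with an estimated correlation). In the glycolysis and hypoxia list 16 of 25 fell and 2 rose, 19 over the list alone (camera adjusted p = 0.00063, adjusted p = 0.368 with an estimated correlation). LDHA, lactate dehydrogenase A, went from 10470 ± 477 to 6295 ± 439, and the glucose transporter SLC2A3 from 19630 ± 1830 to 9267 ± 1640. The 5 tested ribosomal protein genes, of 75 listed, fell, 5 over the list alone (camera adjusted p = 0.00196, adjusted p = 0.348 with an estimated correlation), among them RPSA by 0.62 ± 0.037.

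Junction genes fell in 18 of 22 cases and rose in 0, 18 over the list alone (camera adjusted p = 0.000121, adjusted p = 0.167 with an estimated correlation). E-cadherin CDH1 went from 21210 ± 472 to 10730 ± 374 and EPCAM from 184.2 ± 35.4 to 48.1 ± 7.31. Stem state genes fell in 11 of 16 cases and rose in 2, 13 over the list alone (camera adjusted p = 0.0193, adjusted p = 0.349 with an estimated correlation), and this call was lost without day 8 replicate 3, at 0.0563. G2/M genes fell in 25 of 48 cases and rose in 1, 27 over the list alone (camera adjusted p = 0.00276, adjusted p = 0.663 with an estimated correlation). Unfolded protein response genes fell in 10 of 16 cases and rose in 1, 12 over the list alone (camera adjusted p = 0.00819, adjusted p = 0.348 with an estimated correlation), the chaperone CALR by 0.70 ± 0.037. Angiogenic genes fell in 8 of 16 cases and rose in 1, 9 over the list alone (camera adjusted p = 0.0193, adjusted p = 0.348 with an estimated correlation). PECAM1, an endothelial adhesion molecule, fell from 649.4 ± 22.4 to 241.6 ± 35.2. The number of changed genes at this step depended on the test, being 1987 with limma-voom, 2137 with edgeR on the recovered reads, 2212 with 1 spread for all days and 2459 with DESeq2. Scaling by library totals raised the share of higher calls from 38.0% to 60.5%.

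The last comparison set the end of the protocol, day 8, against the stem state. The deposited genes had been selected for a difference between these days, so that 8889 of 8898 genes were called, 4185 higher and 4704 lower, describes the table rather than the cells. Sizes remain informative. CSH1 rose from 1.2 ± 1.11 to 103100 ± 5690 normalized counts, ADAM12 from 10.9 ± 2.02 to 56850 ± 3150, HTRA4 from 28 ± 33.4 to 138800 ± 7710, LAMA4, a laminin chain, from 2.83 ± 2.07 to 20050 ± 619, and ACAN, the proteoglycan aggrecan, from 2.79 ± 3.66 to 23440 ± 1440. LRP2 fell from 69990 ± 11500 to 76.3 ± 11.3, PODXL from 20950 ± 9310 to 46.2 ± 6.26, CCKBR, a gastrin receptor, from 4157 ± 1180 to 7.33 ± 3.37, and HAPLN1, a hyaluronan link protein, from 2417 ± 1050 to 5.03 ± 4.73. At least 2-fold changes numbered 6566, of which 3079 were rises and 3487 falls. CGA and CDKN1C, among the landmarks fixed beforehand, were not analysed here.

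Of the landmark genes, on the GRCh38 coordinates of GENCODE 29, HLA-G (ENSG00000204632, chromosome 6, 29826967 to 29831125) rose by 6.50 ± 0.318 on the log2 scale (adjusted p = 2.8e-10). MMP2 (ENSG00000087245, chromosome 16, 55389700 to 55506691) rose by 6.44 ± 0.217 (adjusted p = 1.39e-13). ITGA1 (ENSG00000213949, chromosome 5, 52787896 to 52959210) rose by 7.57 ± 0.268 and NOTUM (ENSG00000185269, chromosome 17, 81952507 to 81961840) by 8.08 ± 0.491. The bHLH factor ASCL2 (ENSG00000183734, chromosome 11, 2268495 to 2270952) rose by 3.90 ± 0.266 and EPAS1 (ENSG00000116016, chromosome 2, 46293667 to 46386703) by 3.59 ± 0.151. The syncytial genes SDC1 (ENSG00000115884, chromosome 2, 20200797 to 20225433) and ERVW-1 (ENSG00000242950, chromosome 7, 92468380 to 92477986) rose by 4.70 ± 0.182 and 3.03 ± 0.181. TEAD4 (ENSG00000197905, chromosome 12, 2959330 to 3040673) fell by 5.20 ± 0.172, TP63 (ENSG00000073282, chromosome 3, 189631416 to 189897279) by 3.47 ± 0.241 and MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) by 3.39 ± 0.238. ITGA6, the laminin receptor subunit of progenitors, fell by 1.52 ± 0.146. These genes are annotated as protein coding.

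By list, each of the 29 extravillous genes (camera adjusted p = 1.97e-10, adjusted p = 0.199 with an estimated correlation), 23 syncytiotrophoblast genes (camera adjusted p = 2.8e-08, adjusted p = 0.199 with an estimated correlation) and 30 interferon-response genes (camera adjusted p = 2.05e-07, adjusted p = 0.306 with an estimated correlation) was higher at day 8. TGF-beta feedback genes and targets gave 13 of 19 higher and 6 lower, 19 over the list alone (camera adjusted p = 0.0389, 0.0504 in a fit of these days alone, adjusted p = 0.306 with an estimated correlation), with TGFB2 up from 33.8 ± 33.1 to 423.3 ± 14.2 and CCN2 down from 996.6 ± 315 to 25.6 ± 4.27. Each of the 48 G2/M genes was lower (camera adjusted p = 5.53e-10, adjusted p = 0.408 with an estimated correlation), as were 40 of 41 G1/S genes (camera adjusted p = 7.14e-07, adjusted p = 0.431 with an estimated correlation) and 13 of 16 stem state genes (camera adjusted p = 0.0133, adjusted p = 0.306 with an estimated correlation). DNMT3L, a DNA methylation cofactor of the stem list, was an exception, rising from 16.7 ± 13.3 to 751.9 ± 126. Since the selection left no gene near its day 0 level, nearly all members of any list are called and the direction is what a list's count shows.

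**Figure D3:**
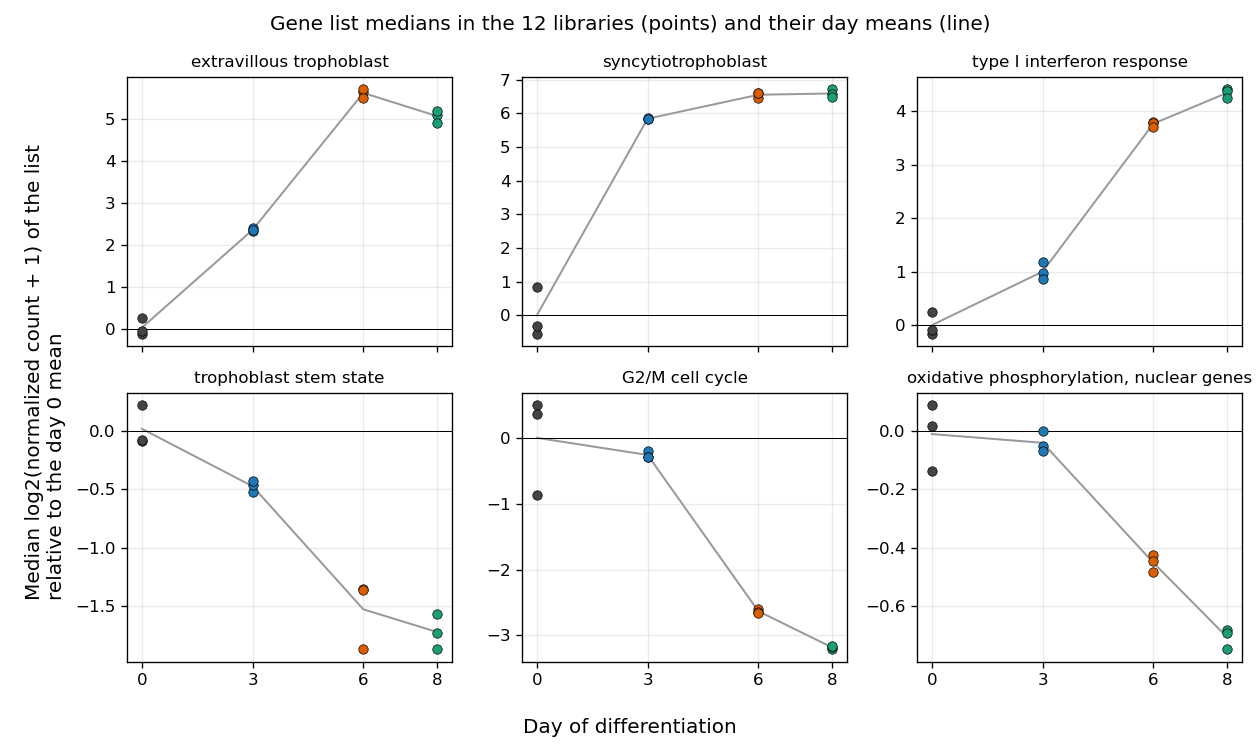
Median log2(normalized count + 1) of the members of 6 gene lists relative to their day 0 mean (vertical, log2 units; the scales differ) at days 0, 3, 6 and 8 (horizontal), each point 1 library and the line joining the means of the points. Syncytiotrophoblast points lie between 5.83 and 5.85 at day 3, when extravillous points lie between 2.32 and 2.39.

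Timing differed between genes. Of the 6566 genes at least 2-fold apart between day 8 and day 0, 4724 (71.9%) were first called against day 0 at day 3, 1666 (25.4%) at day 6 and 176 (2.68%) at day 8. Genes that ended higher had covered a median of 53.8% of their day 8 change by day 3 and 96.6% by day 6, and genes that ended lower 52.4% and 89.8%. SDC1 and ERVW-1 were near their final level at day 3, whereas NOTUM rose by 7.44 ± 0.14 between days 3 and 6. CSH1 rose at both steps, from 1.2 ± 1.11 to 166.9 ± 31.2 normalized counts by day 3 and by 9.55 ± 0.126 on the log2 scale from there to day 6. Without day 0 replicate 1 the numbers first called at days 3, 6 and 8 were 5436, 1199 and 112, and without replicate 3 they were 4143, 2006 and 289.

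Some genes turned back. At day 3, 122 genes peaked and 198 dipped, each by at least 2-fold against both day 0 and day 6. Unchanged simulated groups gave at most 0 such genes over 20 simulations, and independent lists of the same sizes would share 311.5 and 389.4, numbers that cannot be set against the observed ones, because selection by the difference between days 8 and 0 removes genes that return to their starting level. CCR7, a chemokine receptor, rose from 566.7 ± 358 to 3609 ± 62.1 at day 3 and was at 142.2 ± 9.72 at day 6. The transporter genes SLC52A1, SLC22A11 and SLC13A4 and the ketohexokinase gene KHK peaked likewise, SLC22A11 at 4212 ± 122 between 157.8 ± 29.4 and 934 ± 86.7. NES, the intermediate filament nestin, dipped from 3967 ± 1260 to 347.7 ± 30.8 and was at 5537 ± 357 at day 6, and VCAN and HPGD dipped in the same way. At day 6, 87 genes peaked and 55 dipped, against at most 1 in simulation and 55.84 and 58.68 for independent lists. The numbers for independent lists are conditional on the same selection of genes, so nothing is concluded from them. The simulated groups had no difference at either step, so their low counts do not show how many changing genes would appear to turn. CRABP2, a retinoic acid binding protein gene, went from 13.3 ± 5.56 at day 3 to 161.7 ± 17.3 at day 6 and 20.8 ± 3.11 at day 8. IL10RA, an interleukin 10 receptor subunit, went from 35.6 ± 8.12 to 1433 ± 192 and 193.9 ± 62.2, and the serotonin transporter SLC6A4 from 177 ± 5.18 to 3046 ± 55.9 and 998.1 ± 58.8. Both steps use the same libraries of the middle day, so part of these numbers may come from that sharing.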

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

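The TMM factors on recovered reads, pseudocounts and library weights were chosen after seeing the data. edgeR and 1 shared spread had been planned for the main test and became alternatives then, and the other settings were chosen beforehand. Of 323 counts recomputed, 306 stayed within 1.5 times the value reported and 17 did not. List tests kept their side of the threshold in 3754 of 3944 cases, 61 losing a call, 125 gaining 1 and 4 reversing. Many settings alter the fit little, so this share does not measure how firm the list calls are. Among 136 list tests the estimated correlation lost 43 calls, leaving no list called. In the same 136, fry gained 69 calls and reversed 4. Named genes kept theirs in 19007 of 19586 cases, 554 losing a call, 19 gaining 1 and 6 reversing. Directions were compared only where either setting made a call. Changed genes at day 8 against day 6 numbered 2459 with DESeq2, 1987 with limma-voom, 2137 with edgeR on the recovered reads and 2212 with 1 spread for all days. Tested against a 2-fold change, 2253 genes passed at day 3 against day 0, 2154 at day 6 against day 3, 78 at day 8 against day 6 (48.7% of them higher), 4765 at day 8 against day 0 and 4310 at day 6 against day 0. Genes first called at day 6 numbered 1094 under library totals and 2704 with no minimum fold, and those first called at day 8 numbered 362 with library weights and 389 with no minimum fold. With no minimum fold 1321 genes turned at day 3 and 1809 at day 6. Without 1 library at a time, counts ranged from 5137 to 7287 (day 3 against day 0), 6757 to 6994 (day 6 against day 3), 3888 to 4495 (day 8 against day 6), 8641 to 8890 (day 8 against day 0), 7707 to 8569 (day 6 against day 0) and 8829 to 8892 (any day). Genes first called at days 3, 6 and 8 ranged from 4143 to 5436, 1199 to 2006 and 112 to 289, and genes turning at days 3 and 6 from 311 to 331 and 127 to 156. Library totals cover only the table's selected genes. Under the authors' size factors the sums of these genes were 10580365 to 11227326 at day 0 and 19577663 to 20796457 at day 6. Library totals moved the median gene by -0.473, -0.413, 0.131 and -0.754 on the log2 scale and the share of higher calls to 28%, 31.5%, 60.5% and 35.1%, from 46.9%, 49.3%, 38.0% and 47.1%, in the 4 comparisons in the order of the report. Upper quartile scaling moved the median by -0.223 at day 3 and -0.226 at day 8 against day 0, and RLE by 0.177 in the latter. Under library totals the log2 fold change became -0.11 for COX6C at day 3 against day 0, -0.23 for SDC1, -0.23 for ERVW-1 and -0.05 for RPL10 at day 6 against day 3, 0.12 for ITGA1 at day 8 against day 6 and -0.06 for RPL10 at day 8 against day 0. Among lists that fry called, the direction turned for Notch (adjusted p = 0.00556), imprinted genes (0.000124) and cytokines (0.000925) at day 6 against day 3 and for cytokines at day 8 against day 6 (0.0159). With neither test passing it also turned for glycolysis at day 6 against day 3, pregnancy-specific glycoproteins at day 8 against day 6 and immediate early genes at both steps. The cause was not tested for any of these. The labels do not say whether replicate numbers pair the samples. Deviations of libraries with the same number correlated between -0.026 and 0.054 over 18 pairs, others between -0.052 and 0.029 over 36. Not every library correlated best with its own number. Between days 6 and 8 the same-number values were 0.008, 0.044 and 0.054 for replicates 1, 2 and 3. Correlations this small cannot decide whether cultures were paired. With the replicate number as a block 6290, 6950, 4271 and 8893 genes changed. Leaving mitochondrial and ribosomal genes out of the totals was not run, since the scaling does not use totals. The fit of only 2 groups and the test against a 2-fold change were not applied to timing and turning genes. Depth limits the genes near the minimum of 10 normalized counts most, where counting error is largest and small changes may have been missed. Detection was not measured by expression level.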

Other observations

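The tests of the 3 patterns below were chosen only after the results were seen, and the other splits of the libraries were planned.

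Genes of WNT and Notch signalling and of the matrix moved in both directions. At day 3 against day 0, 4 of 13 WNT feedback and target genes rose and 9 fell, 13 adjusted over the list alone (camera adjusted p = 0.3). LEF1, a transcription factor of the pathway, fell from 73.4 ± 19.7 to 4.18 ± 2.3 normalized counts (SD, n = 3 per day) and the receptor gene TNFRSF19 from 469 ± 131 to 10.7 ± 8.32, while LGR4, a receptor for R-spondins, rose from 2315 ± 928 to 11270 ± 208. At day 6 against day 3, 3 of 12 Notch genes rose and 7 fell, 10 over the list alone (camera adjusted p = 0.627). The receptor NOTCH2 rose from 1841 ± 59.6 to 17880 ± 471 as NOTCH3 fell from 1323 ± 66.2 to 275.2 ± 21.1. Integrin genes gave 5 of 16 higher and 8 lower at this step, 14 over the list alone, with a median of -0.28 and an upward test direction (camera adjusted p = 0.983). ITGB4, the integrin subunit of hemidesmosomes, fell from 17850 ± 474 to 3695 ± 213. Of 14 basement membrane genes 6 rose and 7 fell, 13 over the list alone, with a median of -0.17 and a mean of 0.20 (camera adjusted p = 0.983). HSPG2, the proteoglycan perlecan, rose from 12920 ± 282 to 273600 ± 28000 and LAMA4 from 386.1 ± 50.6 to 21330 ± 1040, and LAMA1 fell from 13930 ± 346 to 1456 ± 68.

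Imprinted genes gave 6 of 17 higher and 6 lower at day 3 against day 0 (9 and 6 without day 0 replicate 1, 4 and 7 under library totals), 12 over the list alone (camera adjusted p = 0.763). IGF2, a fetal growth factor, rose from 9211 ± 2970 to 209800 ± 8010, and SNRPN fell from 446.8 ± 433 to 12.7 ± 3.89. Cytokines and chemokines gave 4 of 16 higher and 9 lower at that step, 13 over the list alone (camera adjusted p = 0.391), with TNF down from 183 ± 74.7 to 10.9 ± 3.74 and the chemokine CCL5 up from 3.52 ± 3.06 to 95.8 ± 11.9. Cholesterol synthesis genes gave 4 of 10 higher and 5 lower at day 6 against day 3, 9 over the list alone (camera adjusted p = 0.937), MSMO1 rising from 4373 ± 120 to 6886 ± 100 and TM7SF2 falling from 569.5 ± 72.9 to 152.8 ± 12.7. The erythroid list had 1 tested gene, the embryonic globin HBZ, which rose from 0.803 ± 0.783 to 45 ± 13.5 at day 6. Of 4 tested amnion and early embryonic markers 2 rose and 1 fell at that step (1 and 2 under library totals), 3 over the list alone, and TFAP2B went from 1.17 ± 1.28 to 17.7 ± 9.61.

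Day 0 replicate 1 stood apart from the other day 0 libraries, with higher syncytiotrophoblast and lower cell cycle genes. Cells of a later day mixed into it would place its genes between day 0 and the later days. Of the 662 genes at least 2-fold higher in it, 367, or 55.4%, lay above every other library by a fixed margin. A mixture alone does not account for those genes. The 662 were picked for being high in it, so spread between cultures could also place some there. No like share was computed for the other day 0 libraries. Of the 431 genes at least 2-fold lower, 52, or 12.1%, lay below every other library by that margin, so for most lower genes a mixture cannot be told apart from another cause. A later library under a wrong label is argued against by its Spearman correlations, the lowest with a day 0 library (0.957) exceeding the highest with a later library (0.881) by 0.076. A different state of that culture, a stage between the sampled days, or a mixture together with another difference stays open. No biological explanation was tested, since the design names no difference between the day 0 cultures.

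Of 32 tested mesenchymal and stromal genes, 9 were read nearly only at day 0, with later means at most 10% of the day 0 mean: VIM, SNAI2, TNC, ACTA2, THBS1, LUM, THY1, COL6A3 and AXL. RNA of 1 other cell type would keep them in 1 ratio across the day 0 libraries, and their reads gave a chi-square per degree of freedom of 254 (16 degrees), or 8.81 (10 degrees) for the 6 under 3 normalized counts at every later day, VIM, SNAI2, TNC, ACTA2, LUM and THY1. Among 1000 random sets of other genes at like day 0 levels the medians were 32.3 and 7.33, and 99% and 59.7% of the sets lay at or below the values of the 9 and the 6 genes. The 9 varied more than nearly all such sets, but ordinary genes also departed far from 1 ratio. The chi-square sets the spread between cultures against counting error alone, so it cannot decide for the 9. THBS1, COL6A3 and AXL were also read on later days, with means up to 251, 59.6 and 109. Reads of the trophoblast cells themselves are thus not excluded as the reason for the variation. The 6 varied as ordinary genes did, which decides nothing. RNA of 1 or more other cell types and expression by some of the day 0 trophoblast cells cannot be told apart here.

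Interferon-response genes rose from day 3 to day 6. Library scaling is argued against, since at least 29 of 30 were called higher under each of the 5 scalings tried, with medians between 1.95 and 2.39. Immune cells rich in CD74 would add reads of it, but CD74 fell from 237.8 ± 17.9 to 35.2 ± 6.48. Its log2 fold change of -2.74 lay above that of LAPTM5. Of 5 tested leukocyte markers these 2 fell and 3 rose, with a median of 0.85. CD74 was already read at day 3, so a fall of that level can hide added reads, and immune cells are not excluded. The receptor genes IFNAR1 and IFNAR2 rose too, from 213 ± 8.76 to 1003 ± 86.6 and from 222.2 ± 34.4 to 1884 ± 44.9. What raised these genes was not tested, since the day of differentiation and the time in culture are the same in this design.

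In each comparison of 3 against 3 libraries 1 of 10 splits, the real one, gave as many changed genes, and a share under 0.1 cannot be had. The real splits gave 6130 (day 3 against day 0), 6974 (day 6 against day 3), 4348 (day 8 against day 6), 8889 (day 8 against day 0) and 8339 (day 6 against day 0) genes, and the highest of the other splits gave 0 in each. Every other split mixes libraries of both days in each group, so the difference between days widens its spread and lowers its calls. For day 8 against day 0 the genes were also selected on the real split. Nothing is concluded from these splits. Across the 4 days 1 of 100 drawn divisions, the real one, gave 8888 genes and the highest other 5917, but the genes had been selected on the real days, so this comparison decides nothing.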
